A study of Arabidopsis thaliana with 11 samples.

How the data were processed

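The series lists 11 samples, and the processed file of 1 of them, the RNA-seq library labelled prmt10, was used; the 10 PAS-seq samples were not analysed here. The deposited file holds a score per run of bases on each strand, which is read depth in whole numbers, with negative values for the minus strand. No scaling was seen in the values. Bowtie 0.12.7, TopHat 1.3.0 and the genome build TAIR10 are named in the submitters' processing notes, without the role of each. The filters on mapped reads, the handling of duplicates and of reads with several matches, and the protocol that kept strand are not given in the sources used here. The protocol text attached to this sample, per the labels, describes crosslinking and poly(A) site sequencing, and a protocol for this RNA-seq library is not given in the sources used here. The design foresaw alignments, and the file holds depth instead, so counts of reads and of spliced reads were replaced by sums of depth.

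Depth was summed over bases and divided by 80 nt to give read equivalents, called reads in the text. Of 38167 isolated runs of depth 1, 28600 (74.9%) were exactly 80 nt wide, and the next most frequent width, 8 nt, had 329 runs. The library held 20135853 read equivalents, 49.8% of them on the plus strand. Of 11589 genes with at least 50 reads and no other gene in their span, 11089 (95.7%) had at least 95% of their depth on 1 strand. The strand with more depth was taken as that of the gene, because the gene table gives no strand.

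Gene names and spans came from the gene table of assembly TAIR10.1, in which all 212 gene entries of the lists were found. The spans were used to sum depth, and no position from that table is printed. To check that spans match the file, they were shifted along the chromosome. Unshifted, protein-coding spans held 98.8% of the depth, against 95.3% and 95.2% after a shift of 200 nt to either side and 74.5% and 74.1% after a shift of 1000 nt. Positions in the text are those of the file on TAIR10, counted from 1, and can be off by 1 nt because the file states no counting convention. The table has no exons, so the exon-based quantities of the design were replaced, and the planned ratio of distal to shared 3' segments gave way to the place where depth ends. RPKM, in its usual scaling, is reads on both strands per kb of gene span relative to the reads in protein-coding genes (20200878, with reads in overlapping spans counted in each gene), and it is lower than a value per kb of exon for genes with long introns. Chloroplast and mitochondrial genes were not analysed here.

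Introns were found from depth, as a fall within 1 base to at most 50% of a depth of at least 10, followed by a mirrored rise, with edges within 5-fold of each other and a length of at least 60 nt. Their mean depth was divided by the mean depth of the gene's covered bases outside introns. The main set held introns of at least 100 nt in genes with at least 50 reads and no other gene in their span. The end of depth was the last base with at least 10% of that exon depth. Ends were counted and ranked in genes with at least 50 reads on the strand with more depth and no other gene in their span. The profile used such genes with a span of at least 1000 nt and 1 listed transcript. Sequence copies shared between genes and overlapping genes leave part of the reads uncertain.

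Intervals are at 95%, exact Poisson for reads and quantities made from them and Clopper-Pearson for shares and for the ratio of 2 counts. They cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 is given with its exact Poisson upper bound of 3.69 reads. With 1 library, no p-value was computed. A list's median was placed among 10000 random lists of as many protein-coding genes matched on deciles of gene span, or for introns on deciles of exon depth, and a list was taken to stand apart outside their central 95%.

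The 17 gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. The definitions of introns and ends from depth, and the further settings named as added, were set after the file was seen to hold depth. The rule names every PRMT gene, HLP1, FLC, FCA, FPA and FY, the 2 genes with the most and the 2 with the fewest reads per kb in every other list, the 10 genes with the most reads, the 10 introns with the highest ratio, introns set in advance in genes with known intronic poly(A) sites and, for gene ends, 5 genes at each extreme, applied here to the place where depth ends and to depth beyond the end. The value of 1 gene that the rule names is not reported here. The sixth CPSF30 intron, the longest IBM1 intron, the introns of SCL30A and SR34b, and CCA1 and TOC1 were singled out after their values were seen.

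The procedures for introns and ends were tested on simulated 80-nt reads with levels drawn from the library. Reads were placed evenly at random along exons with sharp ends, whereas depth in the library was uneven. The shares of introns and ends recovered hold for such even depth and can be lower in the library. A gap of 1222 nt without depth in FPA, for example, was not found as an intron. In 500 simulated genes per level, 100% of introns with edge depths of at least 10 were found at a planted intron depth of 10%, and their median measured value was 10.45%. At a planted 30%, 98.0% of such introns were found, with a median of 31.6%. Among all planted introns, including those with lower edge depths, 80.4% and 67.4% were found. Of 5420 introns called, 3 had not been planted. Of 2000 simulated ends, 99.05% were placed within 50 nt. Of 200 simulated lists of 12 genes with no planted change, 5.00% fell outside the central 95%, and 87.0% of lists raised 8-fold fell at or above the 97.5th percentile. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.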

Results

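RNA was measured in Arabidopsis thaliana seedlings of the Col background, a standard laboratory strain. The labels describe 11 samples in 6 groups. Of these, 10 are poly(A) site sequencing libraries (PAS-seq, which reads the 3' ends of polyadenylated RNA), with 2 samples in each of 5 mutant groups, and they were not analysed here. The remaining sample, a single RNA-seq library labelled prmt10, is the subject of all values below. The stated purpose of the series was to examine PRMT10, a protein arginine methyltransferase, in alternative polyadenylation. With 1 library and no library of unmutated plants, genotypes could not be compared and no value has a replicate check. Every interval below is a 95% interval for counting error alone.

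The library labelled prmt10 held 20135853 read equivalents on chromosomes 1 to 5. Most of the 10 genes with the most reads encode light-harvesting proteins of chloroplasts. Of 27444 protein-coding genes, 22738 (82.85%) had at least 1 read and 20193 had at least 10. The 10 genes with the most reads were CAB1, LHB1B2, THI1, LHCA4, LHCB5, LHCA1, LHCA3, DRT112, CAB3 and PSBO1, and together they held 5.67% of the reads. CAB1 (AT1G29930), which encodes a chlorophyll a/b-binding protein, had 189122 reads. LHB1B2 (AT2G34420) followed with 182060 reads and THI1 (AT5G54770), an enzyme of thiamine synthesis, with 133562. Last of the 10, PSBO1 (AT5G66570), a subunit of the oxygen-evolving complex of photosystem II, had 68668. CAB1 and CAB3 are near-identical copies, so the division of reads between them is uncertain. CAB1, LHB1B2 and LHCA4 also share their spans with other genes.

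PRMT10 RNA was detected in the library labelled prmt10. PRMT10 (AT1G04870) had 86 reads (68.8 to 106) and an RPKM of 1.645 (1.32 to 2.03), at the 38.8th percentile of all protein-coding genes. All 9 genes of the PRMT family, which methylate arginine residues of proteins, were detected, and 7 of the other members had a higher RPKM than PRMT10. PRMT11 (AT4G29510) was the highest at 18.1 (16.9 to 19.3). Its ratio to PRMT10 was 11-fold (8.81 to 13.9) by gene span and 6.65-fold (5.33 to 8.40) by covered bases, a scaling added after the data were seen. PRMT7 (AT4G16570), at 1.35 (1.115 to 1.62), had a ratio to PRMT10 of 0.822 (0.616 to 1.1) per kb of gene span, within counting error of equal, and of 0.582 (0.436 to 0.780) per kb of covered bases, so that whether the pair differed depended on the scaling.

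The remaining family members lay between these extremes. PRMT4B (AT3G06930) reached an RPKM of 4.94, SKB1 (AT4G31120, also known as PRMT5) 4.47, PRMT3 (AT3G12270) 4.38, PRMT1A (AT2G19670) 3.62, PRMT4A (AT5G49020) 3.51 and PRMT6 (AT3G20020) 2.565. The lowest ratio to PRMT10 among these was that of PRMT6, at 1.56 (1.21 to 2.02), and 37.0 of its reads lay on the strand with less depth. PRMT11, PRMT1A, PRMT3, PRMT4A and SKB1 each overlap 1 other gene, so part of their reads is uncertain. The median RPKM of the family, 3.62, lay at the 24.6th percentile of random lists matched on gene length, at the 50.2nd of unmatched ones and, among genes that overlap no other gene, at the 12.9th. Per kb of covered bases instead of gene span, PRMT10 had a value of 4.07.

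Of the 86 PRMT10 reads, 85 lay on the minus strand of chromosome 1, in 6 separate blocks, and 1 lay on the other strand. From the 5' side, the blocks ran from 1375634 to 1375383, from 1375221 to 1375029, from 1374847 to 1374742, from 1374439 to 1374248, from 1374108 to 1373989 and from 1373656 to 1373546 (TAIR10). They held 8.275, 18.95, 10.1, 28.5, 16.2 and 3.00 read equivalents. The first 5 blocks had maximum depths of 8 to 18, and the block nearest the 3' end had a maximum of 3. The labels give neither the allele nor the position of the mutation, and exon positions were not used here, so no block can be assigned to a part of the transcript that the mutation would remove.

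**Figure D1:**
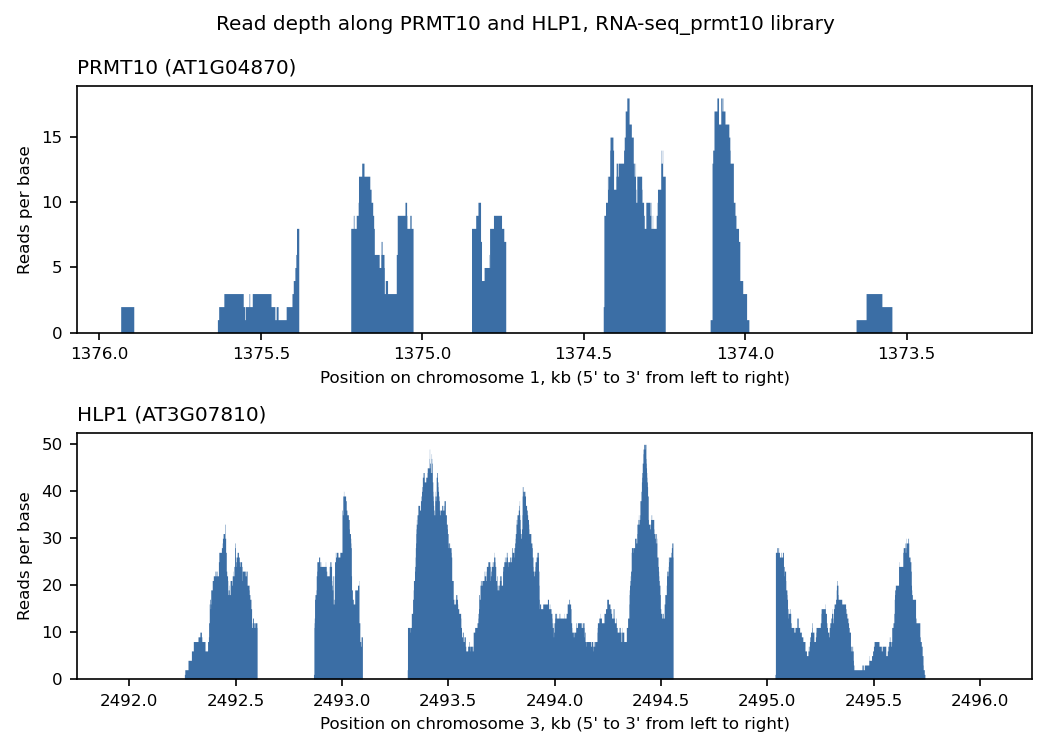
Read depth per base (vertical axis, reads) against position in kb (horizontal axis, 5' to 3' from left to right) on the strand with more depth for PRMT10 on chromosome 1 and HLP1 on chromosome 3, in the 1 RNA-seq library. PRMT10 has 6 blocks, the one nearest the 3' end with 3.00 read equivalents, and the depth at the far left of the upper panel lies outside its span; HLP1 has 4 blocks, of which the longest holds 342.5.

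HLP1, the RNA-binding protein for which PAS-seq mutants are listed in the series, and its relatives of the hnRNP A/B type were all detected. HLP1 (AT3G07810, for which the gene table gives no symbol) had 592 reads (545 to 642) and an RPKM of 7.92 (7.295 to 8.585), the lowest of the 6 genes in its list. AT2G33410 was the highest at 33.0 (31.3 to 34.9), followed by AT4G26650 at 25.8 (24.6 to 27.0), and AT5G55550 reached 10.6 (9.72 to 11.5). The list's median of 15.1 lay at the 93.1st percentile of random lists, inside their central 95%.

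Genes of the cleavage and polyadenylation machinery, which cuts and tails pre-mRNA, were detected with 2 exceptions. Of the 27 genes in the list, 25 had reads. Genes of nuclear poly(A)-binding proteins led the list, AT5G10350 (PABN3) with an RPKM of 22.3 (21.1 to 23.65) and PABN1 (AT5G51120) with 22.0 (20.7 to 23.45). PAPS3 (AT3G06560), a poly(A) polymerase, and CLPS5 (AT5G39930) had 0 reads, which allows up to 0.0639 and 0.0789 RPKM. FY (AT5G13480), a subunit that acts with FCA, had 185 reads (159 to 214) and an RPKM of 1.64 (1.415 to 1.90). The median of the list was 4.67, at the 35.8th percentile of random lists matched on length and at the 68.9th of unmatched ones.

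Among the regulators of flowering time, FLC (AT5G10140), a MADS-box repressor of flowering, had 226 reads. Its RPKM was 1.85 by gene span, at the 40.15th percentile of protein-coding genes, and 8.77 by covered bases. FLC overlaps 1 other gene, and 1 of its reads lay on the strand with less depth. SVP (AT2G22540), another MADS-box repressor, had the highest RPKM of the 7 genes of the FLC clade and SVP, 26.2 (25.1 to 27.3), and MAF1 (AT1G77080, also known as FLM) followed with 9.19 (8.59 to 9.815). MAF5 (AT5G65080) and MAF4 (AT5G65070) were the lowest, at 0.174 (0.103 to 0.275) and 0.173 (0.0945 to 0.290). The list's median of 2.79 lay at the 16.4th percentile of random lists matched on length and at the 40.3rd of unmatched ones. Per kb of covered bases the list lay at the 52.9th percentile, and among genes that overlap no other gene at the 51.4th.

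All 8 autonomous pathway genes, which lower FLC, were detected. FVE (AT2G19520) reached an RPKM of 10.8 (10.1 to 11.5) and FLK (AT3G04610) 9.37 (8.75 to 10.03), while FCA (AT4G16280) had 3.55 (3.28 to 3.85) from 602 reads and FY was the lowest. FPA (AT2G43410), which overlaps 2 other genes, had 460 reads and an RPKM of 3.79 (3.45 to 4.15). All 15 activators of FLC were detected, from VIP4 (AT5G61150) at 18.18 (17.3 to 19.1) and VIP3 (AT4G29830) at 14.2 (13.0 to 15.5) to FES1 (AT2G33835) at 4.09 (3.595 to 4.63) and ATX1 (AT2G31650) at 1.05 (0.8905 to 1.23). The medians of these lists, 4.42 and 6.295, lay at the 37.0th and 69.6th percentiles of random lists. The autonomous pathway list lay at the 57.1st percentile of unmatched lists and at the 56.3rd among genes that overlap no other gene.

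Photoperiod genes and floral integrators had a low median against random lists matched on length. Of the 12 genes, 10 had reads. AGL20 (AT2G45660, also known as SOC1) was an exception at an RPKM of 24.9 (23.8 to 26.1), and CDF1 (AT5G62430), a repressor of CO transcription, had 12.9 (11.8 to 14.1). AP1 (AT1G69120) and TSF (AT4G20370) had 0 reads, which allows up to 0.0450 and 0.0815 RPKM. The list's median of 0.572 lay at the 0.400th percentile of random lists matched on length. Against unmatched random lists it lay at the 5.41st percentile, inside the central 95%, and per kb of covered bases and among genes that overlap no other gene at the 2.30th and 1.65th, outside it.

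Clock genes were detected throughout, and the clock-regulated glycine-rich RNA-binding proteins were among the most abundant transcripts of the library. GRP7 (AT2G21660) had 14426 reads and an RPKM of 484.5 (477 to 492.5), and CCR1 (AT4G39260, also known as GRP8) had 4790 reads and an RPKM of 171 (166 to 176). RVE8 (AT3G09600) and LHY (AT1G01060), a morning transcription factor of the clock, were the lowest of the 12, at 2.87 (2.44 to 3.35) and 1.53 (1.28 to 1.80). The median of 10.9 lay at the 96.6th percentile of random lists, inside their central 95%.

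Nuclear genes for photosynthesis formed the most abundant of the 17 lists. All 22 members had an RPKM above the median of detected genes, 5.63, from CAB1 at 7611 (7577 to 7646) and LHCA4 (AT3G47470) at 3378 (3358 to 3397) to SBPASE (AT3G55800), an enzyme of the Calvin cycle, at 166 (162 to 169.7) and RBCS1B (AT5G38430), a small subunit of Rubisco, at 25.9 (24.4 to 27.5). RBCS1B shares near-identical sequence with its neighbours, so its level is uncertain. The list's median of 1308 was above that of every random list. The list of reference genes was also above every random list, with a median of 76.4 and all 11 members detected, from UBQ10 (AT4G05320), a ubiquitin gene, at 527 (521 to 534) and AT5G60390, an elongation factor gene, at 217 (213 to 221) to PEX4 (AT5G25760) at 11.6 (10.5 to 12.8) and AT2G28390 at 6.54 (5.999 to 7.115). Of the reads of PEX4, which overlaps 1 other gene, 32.5 lay on the strand with less depth.

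Root transcripts were present in the library. PYK10 (AT3G09260), a beta-glucosidase of roots, had 63642 reads and an RPKM of 953 (946 to 961), although it overlaps 1 other gene, and BGLU21 (AT1G66270) had 14.6 (13.7 to 15.5). SHV2 (AT5G49270), a gene of root hair growth, had 0.393 (0.243 to 0.600) and NRT2:1 (AT1G08090), a nitrate transporter, had 1 read. The root list's median of 3.52 lay at the 32.9th percentile of random lists.

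Among seed and flower markers, levels ranged from abundant to undetected. The seed storage genes CRA1 (AT5G44120) and CRU3 (AT4G28520) had 1554 and 981 reads and RPKM values of 36.65 (34.85 to 38.5) and 21.7 (20.3 to 23.1), whereas the related CRU2 (AT1G03880) had 1 read and SESA4 (AT4G27170) had 0. The seed list's median of 1.55 lay at the 65.8th percentile of random lists of similarly short genes and at the 22.4th of unmatched ones. Of 10 flower and pollen markers, TUA1 (AT1G64740), a tubulin gene, was the highest at 16.2 (15.1 to 17.35) and ACT12 (AT3G46520), an actin gene, reached 4.19 (3.72 to 4.72). AG (AT4G18960), a floral organ identity gene, had 1 read and VGD1 (AT2G47040) had 0. TUA1 overlaps 2 other genes and ACT12 overlaps 1. The median of 0.387 lay at the 0.330th percentile of random lists matched on length and at the 4.38th of unmatched ones.

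Stress markers ranged widely. TCH4 (AT5G57560), a touch-induced cell wall enzyme, had an RPKM of 171.5 (167 to 176) and COR47 (AT1G20440), a dehydrin of cold-treated plants, had 145 (141.5 to 148). PR1 (AT2G14610), a marker of salicylic acid responses, had 6 reads and PDF1.2 (AT5G44420), a marker of jasmonate responses, had 0, which allows up to 0.272 RPKM. The median of the 20 genes, 7.90, lay at the 96.9th percentile of random lists, and among genes that overlap no other gene at the 99.1st. Markers of UV and DNA damage, included because the labels' protocols mention UV irradiation for another assay, were also measured. TT4 (AT5G13930), the chalcone synthase gene, had an RPKM of 8.66 (7.73 to 9.68), PARP2 (AT4G02390) 2.475 (2.16 to 2.82) and AT1G07500 1.42 (0.643 to 2.93). The median over all 6 genes of this list, 1.81, lay at the 34.3rd percentile of random lists.

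SR proteins, which regulate splicing, were expressed above most genes. Of the 18 genes, 17 lay above the median of detected genes. RS2Z33 (AT2G37340) reached an RPKM of 62.9 (60.75 to 65.1) and RS31 (AT3G61860) 32.35 (30.75 to 34.0), against 5.84 (5.30 to 6.42) for SR34a (AT3G49430) and 0.517 (0.343 to 0.747) for SCL28 (AT5G18810). The median of 15.3 lay at the 99.5th percentile of random lists, and among genes that overlap no other gene at the 94.1st, inside the central 95%.

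**Figure D2:**
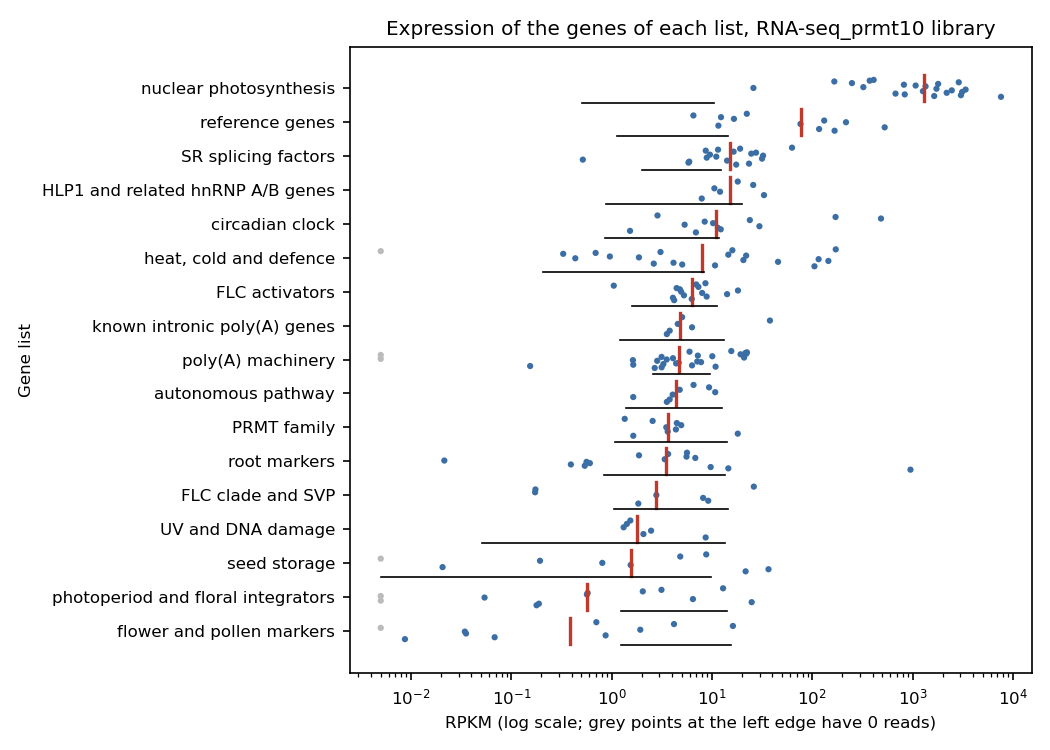
RPKM on a log scale (horizontal axis) of each gene (points) in the 17 gene lists (vertical axis), in the 1 RNA-seq library; red bars mark list medians and black lines the central 95% of medians of 10000 random lists matched on gene length. The photosynthesis median of 1308, the reference gene median of 76.4 and the SR median of 15.3 lie to the right of their lines, and the medians of the photoperiod list, 0.572, and the flower and pollen list, 0.387, lie to the left.

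Introns were examined because transcripts that end inside an intron leave reads there. FCA, which is known to be polyadenylated within the third intron of its transcript, was among the genes chosen in advance. The third intron found from depth, on chromosome 4 from 9211512 to 9213586 (2075 nt), held 78.7 read equivalents, a mean depth of 22.8% of the gene's exons (18.1 to 28.5). Relative to the depth at its edges the value was 15.2%. Its depth was continuous with the exon on the 5' side as far as position 9213247 and was broken into smaller blocks beyond it. The highest ratio in another FCA intron was 3.82%, from 1.075 read equivalents.

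Other genes with known intronic poly(A) sites had lower point values than FCA in the introns chosen in advance, as numbered from depth. For FPA no comparison is made, because the intron chosen may not have been found. For the seventh intron found in IBM1 the interval overlaps that of FCA, so a lower ratio is not shown for that intron. The second intron found in CPSF30 (AT1G30460), a poly(A) factor, had a length of 970 nt and a ratio of 2.81% (1.08 to 5.51), whereas its sixth, of 193 nt, had 23.15% (11.9 to 40.3). In IBM1 (AT3G07610), a histone demethylase gene, the seventh intron found had 0.130% (0 to 19.2), from 0.025 read equivalents. The longest, of 1974 nt, had 3.41% (1.83 to 5.86), an interval below that of FCA. In FPA, no depth lay between 18029349 and 18030570 on chromosome 2. This gap was not found as an intron, so it has no ratio. The first intron found, further 3', had 0.0504% (0 to 14.9), from 0.0125 read equivalents. Of the introns of AT4G33150 (LKR/SDH) the highest ratio was 2.36% (0.529 to 7.50), and of those of AT1G58602 (RPP7), a disease resistance gene, it was 6.87% (4.55 to 10.2). The median RPKM of the 6 genes in this list, 4.81, lay at the 45.8th percentile of random lists. Introns are numbered as they were found from depth, and exon annotation was not used here, so that these numbers can differ from the annotated ones.

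**Figure D3:**
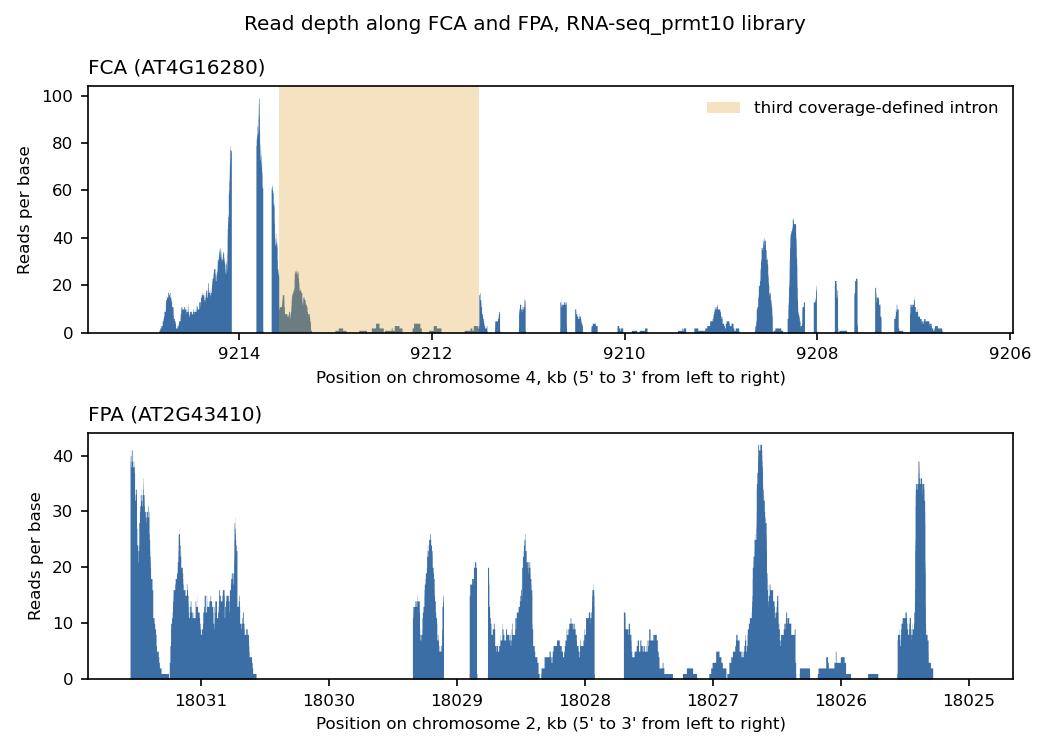
Read depth per base (vertical axis, reads) against position in kb (horizontal axis, 5' to 3' from left to right) on the strand with more depth for FCA on chromosome 4 and FPA on chromosome 2, in the 1 RNA-seq library; shading marks the third intron found in FCA, which held 78.7 read equivalents. In FPA, no depth lay between 18029349 and 18030570, and the depth at the far left of its panel lies outside its span.

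Across the library, 18902 introns of at least 100 nt were found in 6962 genes, with a median ratio of 0.359%. A ratio of at least 10% was found for 747 of them, 3.95% (3.68 to 4.24). MYB48 (AT3G46130), a transcription factor gene, had the highest ratio at 104% (59.1 to 162.5), with 17.41 read equivalents in 103 nt. AT4G12680 followed with 98.3%, then CCR1 with 84.75% (79.5 to 90.2), UBC9 (AT4G27960) with 84.1%, AT3G03770 with 81.5%, AT4G38120 with 68.4%, AT5G39790 with 65.9%, AT2G25590 with 64.4%, GRP7 with 61.9% (59.5 to 64.35) and AT5G17440 with 61.1%. Relative to the edges of the intron, all 10 ratios were lower and their order differed, with 48.0% for AT4G12680, 38.9% for AT5G39790, 38.4% for AT5G17440, 34.7% for MYB48, 31.9% for AT3G03770, 30.6% for AT2G25590, 20.9% for CCR1, 20.2% for GRP7, 15.2% for AT4G38120 and 13.5% for UBC9. The search accepted no ratio to the edges above 50%, so lower values were fixed in advance for these 10 introns. Because an intron is found by a fall in depth, introns retained in most transcripts were missed.

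Intron ratios were also compared by list, with each gene entered as the median over its introns. The median over 9 clock genes was 3.96%, at the 99.5th percentile of random lists matched on exon depth. Of these genes, 5 lay at or above that value, CCR1, GRP7, CCA1 (AT2G46830) with 8.23%, RVE8 with 5.38% and TOC1 (AT5G61380) with 3.96%, and the other 4 lay at 0.617% or less. Without GRP7 and CCR1, the 2 highest, left out after the data were seen, the median was 0.617%, at the 51.4th percentile of random lists, and at the 79.3rd when the 2 highest genes were left out of each random list too, both inside the central 95%. The median over 10 SR genes was 0.177%, at the 2.17th percentile of matched lists and at the 2.69th of unmatched ones, the latter inside the central 95%. Among the SR genes, 2 of 33 introns had a ratio of at least 10%, intron 3 of SCL30A (AT3G13570) with 50.5% (32.6 to 75.6), or 24.4% of the depth at its edges, and intron 1 of SR34b (AT4G02430) with 16.2% (6.01 to 35.6). Many ratios of SR introns rested on a fraction of a read, as in intron 5 of SCL30A, with 0.127% (0 to 12.5) from 0.0375 read equivalents. The low placing therefore does not show that SR transcripts held less intronic RNA than others. The median over 14 genes of the poly(A) machinery was 0.229%, at the 4.78th percentile of matched lists. The medians of the other lists with at least 3 genes lay between the 30.8th and the 90.6th percentiles, and those of the photosynthesis, seed storage, flower and pollen, and UV lists rested on fewer genes and were not set against random lists.

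Read depth often stopped before the end of the gene span given by the table. In all, 11551 genes had at least 50 reads on the strand with more depth and no other gene in their span. Of these 11551 genes, 5605 (48.5%) lost depth at least 100 nt before that end, and the median distance was 97.0 nt. With a minimum of 200 nt, 1604 genes did. PRMT10 lost depth 312 nt before its end, CPSF30 491 nt, HLP1 221 nt, FCA 116 nt, FLC 91.0 nt, IBM1 75.0 nt, FY 47.0 nt and FPA 36.0 nt. FLC and FPA overlap other genes and lie outside the set of 11551. Among the 11551 genes, the 5 with the greatest distance were AT1G58848 with 4868 nt, BXL3 (AT5G09730), a beta-xylosidase gene, with 3250 nt, AT3G20760 with 3116 nt, AT3G29130 with 2670 nt and AT5G24940 with 2401 nt. The spans of these 5 genes were 5363, 3449, 3199, 4471 and 2459 nt, in the same order. In AT1G58848, BXL3, AT3G20760 and AT5G24940, depth therefore lay only near the edge taken as the 5' end, and an early end is not shown. The strand was taken from depth, so a wrongly assigned strand would exchange the ends of a gene. Neither this nor reads running in from a neighbouring gene was tested. Ends of different transcripts of a gene were not used here, so a shorter transcript and uneven depth also look alike in these values.

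Depth beyond the end of the span was rare. Among 1370 genes of the same set with at least 1000 nt to the next gene and a mean depth of at least 5 in their last 200 nt, the median depth of the 200 nt beyond the end was 0% of that of the last 200 nt, and it reached at least 50% in 11 genes. AT3G24480 had the highest ratio, 9.91, followed by HSL2 (AT5G65710), a receptor-like kinase gene, with 5.675, PUB8 (AT4G21350) with 2.96, AT1G67310 with 2.72 and FLP1 (AT4G31380) with 2.31.

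Along the gene span, reads were weighted towards the 3' end. Over 5478 genes with 1 listed transcript, with each span divided into 10 equal bins from 5' to 3', bin 1 held 4.33% of the depth, bin 8 15.2%, bin 9 15.4% and bin 10 7.17%, and bins 6 to 10 together held 60.01%.

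**Figure D4:**
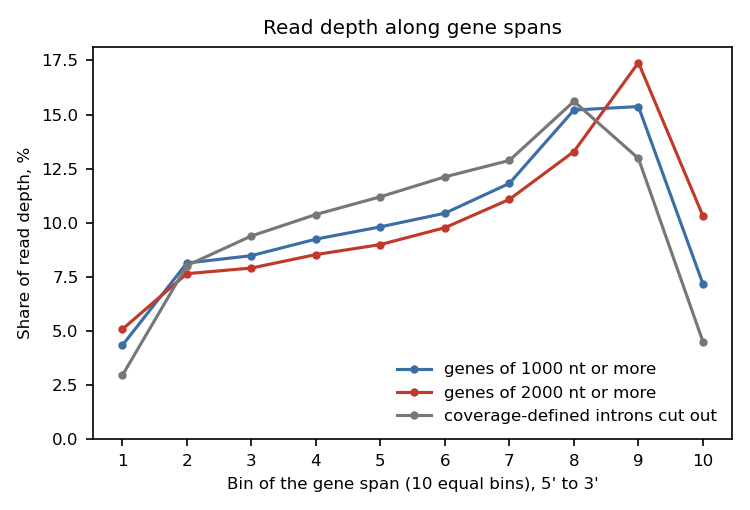
Share of read depth in percent (vertical axis) in each of 10 equal bins of the gene span from 5' to 3' (horizontal axis), summed over genes with 1 listed transcript in the 1 RNA-seq library; lines show genes of at least 1000 nt, genes of at least 2000 nt, and genes with introns found from depth removed. For genes of at least 1000 nt, the share is 4.33% in bin 1 and 15.4% in bin 9.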

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

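The minimum distance from genes was chosen after the data were seen, and no test of an explanation was run in this part.

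Depth far from any gene drew attention because it lies outside the quantities compared and, with no control library, above what a count of 0 allows. On the minus strand of chromosome 1, positions 11670581 to 11670761 held 2520 read equivalents (2423 to 2620). On the minus strand of chromosome 2, positions 6455548 to 6455733 held 637 (588.5 to 688), and on its plus strand positions 14164476 to 14164624 held 182 (156.5 to 210.4). No depth lay on the opposite strand of these 3 blocks. In all, 1849 blocks more than 500 nt from any gene of the table held 8211 read equivalents, 0.0408% of the depth.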

How the results depend on the processing

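The settings of covered bases, of genes without overlap, of the strand with more depth, of intron edges, of a 60-nt minimum, of a 5% end, of edge depths of 30, of intron lists without their highest genes or unmatched, and of removed introns or several transcripts were added after the data were seen; the cause was not tested unless stated. No paired analysis was possible because only 1 library was used, although the PAS-seq groups share replicate numbers. Detected genes numbered 22738 in the main setting, 20193 at 10 reads and 22737 on 1 strand. The number of lists outside the central 95% of random lists was 5, and 3 with unmatched random lists, where the photoperiod and the flower and pollen lists moved inside. Among genes without overlap it was again 5, but the SR list moved inside and the stress list outside. By intron ratio, the clock list moved inside without GRP7 and CCR1, and the SR list with unmatched random lists. PRMT10 had 4.07 RPKM per covered kb against 1.645, since fewer bases were counted. The share of introns at 10% or more was 3.36% in genes with 200 reads and 3.18% with edge depths of 30, against 3.95%, and stayed within the interval in the 3 other settings. Genes losing depth early fell to 1604 at 200 nt, a stricter limit. The depth in bins 6 to 10 of the gene span was 61.9% in genes of 2000 nt, 58.1% with introns removed and 60.8% with any number of transcripts. Relative to their edges, the ratios of FCA, GRP7 and CCR1 introns were 15.2%, 20.2% and 20.9%. Collapsing duplicates, reads of unique match, assignment by midpoint, and reads overlapping an intron were not run, because depth holds no single reads. The annotated strand was not run, because none is given.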

Other observations

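All tests of an explanation in this part were chosen after the result was seen, and the percentiles of the GRP7 and CCR1 introns likewise.

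Reads on the strand with less depth were rare. The strand of a gene was taken from depth, so these shares are the lowest possible. A gene with reads only opposite to its true strand would count as having none. Of 11589 genes with at least 50 reads and no other gene in their span, 6685 (57.7%) had no read on the strand with less depth, and that strand held 0.306% of the depth. In 258 genes it held at least 10%. RPS15A (AT1G07770), a ribosomal protein gene, had the most such reads, 416, which is 4.61% of its total. MEE9 (AT1G60870) had 384 (15.6%), AT4G18670 382 (33.4%), NRT2.7 (AT5G14570), a nitrate transporter gene, 368 (37.5%) and UGT71C5 (AT1G07240), a glycosyltransferase gene, 314 (38.1%).

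The first introns of GRP7 and CCR1 resembled each other in their reads. Among 1453 introns of genes in the top 10% of exon depth, whose median ratio was 0.322%, GRP7 lay at the 99.9th and CCR1 at the 100th percentile. By the ratio to the edges they lay at the 95.5th and 95.8th percentiles, inside the central 95%. Of their reads, 34.1% (32.3 to 36.0) and 36.2% (33.2 to 39.3) lay in the 50% of the intron nearest the 5' edge. CCR1 and GRP7 were picked for their ratio, so these percentiles describe them and test nothing.

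Few PRMT10 reads lay near its 3' end, with 3 of 85 reads (3.53%, 0.734 to 9.97) in the 20% of its span nearest that end. Counting error around the median share in 1502 genes of like span and reads is argued against, because that share would give 19.7 reads, above the upper bound of 8.77. This shows only a share below that median, since the central 95% of such genes ran from 1.14% to 61.2% and 70 were as low. Uneven depth common to such genes may account for the few reads, since PRMT10 lay at the 4.66th percentile of them, inside the central 95%. For the nearest 25% it lay at the 2.46th percentile and for the nearest 33.3% at the 10.05th, so the placing depends on the part chosen. A lost or altered 3' end of the transcript in the mutant stays open, because the 3 reads have no library of unmutated plants beside them and the labels do not place the mutation.

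The reads in the third FCA intron exceeded those in its other introns, and unspliced precursor along the whole gene is argued against, because the other 8 introns found had a pooled ratio of 0.661%, with an upper bound of 3.06%, against 22.8%. Depth common to long introns and a feature of FCA alone cannot be told apart, because FCA lay at the 97.6th percentile of 165 introns of at least 1000 nt (93.9 to 99.3), and by the ratio to the edges at percentile 93.33. Transcripts that end inside the intron are a candidate explanation, since 80.01% (69.2 to 88.0) of its reads lay in the 50% nearest the 5' edge and covered exon depth was 24.8 upstream and 8.69 downstream, a ratio of 0.350 (0.294 to 0.418) at the 1.87th percentile of 3374 genes split at their longest intron. Without an upstream block of 73 nt with a mean depth of 77.9 the ratio was 0.432 (0.357 to 0.5225), for which other genes give no equal comparison because they kept all their blocks. Depth was uneven, and blocks 22 and 24 from the 5' side, downstream of the intron, had mean depths of 22.5 and 24.0 against 17.56 in block 1, which an even loss of downstream RNA does not give, so this explanation stays open; no biological difference between groups was tested, as there was 1 library.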
